A study of Homo sapiens with 12 samples.

How the data were processed

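RNA from cells of 2 human lung epithelial lines was hybridised to Illumina bead arrays, and 12 arrays from 1 chip were deposited. A549 is a line from a lung adenocarcinoma with traits of alveolar epithelium, and BEAS-2B is an immortalised line from normal bronchial epithelium. Per the labels, cells were kept without serum overnight and then received medium alone or an extract of poultry dust at 0.25% for 1 h or 6 h. Each of the 6 groups (line by condition) has 2 arrays, numbered 1 and 2 in the sample titles. The labels give no time point for the control arrays, and they do not say whether the numbers mark separate cultures, so a p-value here measures the spread between these arrays, part of which can be technical.

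The authors deposited a table of probe intensity values read out by GenomeStudio 2011.1 (submitters' processing notes), as the mean bead signal with no background subtracted and no normalization between arrays. The same deposited table gives a detection p-value per probe and array, in steps of 1 in 770, the share of negative control signals above the probe. Also deposited is a matrix of linear intensity values. Its medians ran from 87.60 to 87.65 and its maximum was 27824.9 on each of the 12 arrays. Its rank correlation with the unnormalized signal of each array was 1. Quantile normalization without background subtraction gives such values. The 24 columns of bead numbers and bead standard errors were not used. Of 47320 probes, 30112 carry 1 gene symbol, 8 carry several and 17200 carry none in the probe table supplied with the series. By gene number, 30073 of the symbols were found in the RefSeq table, and 0 were changed. Probes without a symbol stayed in the tests under their own IDs and are called unnamed here.

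Values were computed from the unnormalized signals with R 4.3.3 and limma 3.58.1. The neqc procedure was used: normexp background correction, an offset of 16, quantile normalization and log2. The deposited table holds no negative control probes, so their mean and spread were inferred from the detection p-values. Probes with a detection p under 0.05 on at least 2 of the 12 arrays were kept (24467 probes). For the 3421 genes with over 1 such probe, the probe with the highest mean over all arrays was used, chosen without regard to groups, and this can pick a probe that also binds related transcripts. That left 20060 features, of which 13035 are named genes and 7025 are unnamed probes. Between 17730 and 19453 probes were detected per array, the median unnormalized signal ran from 79.5 to 95.0, and the dimmest detected probe lay between 5.18 and 5.32 on the log2 scale. The number of arrays limits the precision: the median standard error of a log2 change was 0.258.

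One limma model with a mean for each of the 6 groups was fitted to all 12 arrays (6 residual and 4.71 prior degrees of freedom). Each gene's variance was shared by all groups and moderated by empirical Bayes. A p-value in 1 line therefore rests in part on the spread in the other. The 9 comparisons were dust extract against control at each time in each line, 6 h against 1 h in each line, the difference between lines in the change at each time, and the untreated lines. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. Changes are given on the log2 scale with their standard error (SE), from 2 arrays per group. Where neither array of the dimmer group detected a probe, its fold is given as a lower bound, computed against the dimmest detected probe of those arrays. The overlap of genes that passed in the 2 lines was tested with Fisher's exact test, two-sided.

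The replicate numbers were checked as a possible pairing. Within A549, deviations from the group means correlated across genes between arrays with the same number by 0.404 to 0.468, and within BEAS-2B by 0.528 to 0.645. Between lines the same correlations ran from -0.05 to 0.05. In a principal component analysis the first component (72.3% of the variance) separated the lines, the second (8.32%) the numbers within BEAS-2B and the third (4.30%) the numbers within A549. The labels do not state a pairing, so the model without one stays as fixed before the data were examined. Beside its counts stand those with the number as a block within each line (in the fit of the untreated lines, the number was a block across lines, and since the numbers showed no pairing between lines that count is not given). This blocked model had 4 residual and 5.67 prior degrees of freedom.

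Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01 and adjustment over the 27 lists within each comparison. The calls were repeated with a correlation estimated from the residuals, and fry tested each list against no change. The lists cover chemokines, interleukins and other cytokines, NF-kB components and feedback regulators, immediate early transcription factors, early response genes of mRNA decay and growth arrest, MAPK phosphatases with receptor tyrosine kinase feedback, EGF receptor ligands, pattern recognition and protease receptors, adhesion molecules with inflammatory enzymes, interferon-stimulated genes, aryl hydrocarbon receptor targets and NRF2 targets. Further lists cover the unfolded protein and integrated stress response, cytosolic heat shock proteins, metallothioneins, the cell cycle, cholesterol synthesis, hypoxia and glycolysis, antimicrobial, acute phase and mucin genes, TGF-beta and YAP responsive genes, JAK-STAT feedback, ribosomal proteins, alveolar type II and secretory markers, airway basal and keratin markers, epithelial junctions, mesenchymal markers, and blood leukocyte and macrophage markers.

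The lists, the model, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per dust comparison, the 10 largest rises and 10 largest falls among named genes that passed, lay on the same side of both control arrays on both treated arrays and were detected on both arrays of the brighter group. It takes the 8 largest each way in the other comparisons, up to 4 members that passed per list and comparison, and a panel of 12 genes in every comparison (CXCL8, IL6, ICAM1, PTGS2, TNFAIP3, CXCL1, CCL20, EGR1, FOS, ATF3, HMOX1 and CYP1A1), with fewer printed where a paragraph summarises the rest. Genes named from the blocked model follow the same rule, and that use was decided after the values were seen.

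The alternatives were quantile normalization without background correction, median centring in place of quantile normalization, the deposited normalized matrix, no filter, a stricter filter (detection p under 0.01 on both arrays of a group), an intensity trend in the variance, array weights, each line fitted alone, all probes, the replicate block, leaving out each array in turn, and an overlap threshold of 0.01. Leaving out all BEAS-2B arrays of one number was added after the data were seen. Both models were tested on simulated data of 20060 genes in which 200 were changed (10 draws per dust comparison). Without a block, 8.66% to 12.2% of changes of 1 (log2) passed, 87.3% to 88.8% of changes of 2 and 96.7% to 98.5% of changes of 3, with at most 0.152% false calls. With the block, 74.5% to 77.6% of changes of 1 passed and 99.9% to 100% of changes of 2, with 5.01% to 6.87% false calls. The simulated arrays carried the fitted effects of the replicate numbers and the blocked model's spread. The block was therefore true by construction, and its gain there says nothing on whether the numbers mark a pairing. The measured NF-kB genes were also raised by 1 in the treated group. Levels of the interferon-stimulated list were compared with 10000 random lists of the same size, each member replaced by a gene from the same of 20 bins of mean level.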

Results

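The arrays measured mRNA in A549 and BEAS-2B lung epithelial cells that had received medium alone or a 0.25% extract of poultry dust for 1 h or 6 h, with 2 arrays in each of the 6 groups. The series title asks about inflammatory mediators in lung epithelial cells exposed to organic dust, and about A549 against BEAS-2B. Between 37.5% and 41.1% of the probes were detected on each of the 12 arrays. Replicates correlated across genes by 0.980 to 0.982 in the A549 groups and by 0.965 to 0.972 in the BEAS-2B groups. Between the replicates of a BEAS-2B group 984 to 1229 genes lay over 2-fold apart, against 427 to 544 in A549.

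In A549, the first comparison asked what 1 h of dust extract changed. The features that passed, 18 of 20060, were all higher, among them the transcription factor genes FOSB and EGR1 and the chemokine genes CCL20 and CXCL8. FOSB, a member of the AP-1 family, rose by 6.40 (SE 0.35, adjusted p = 4.35e-05) from a control level that neither array detected, which makes it at least 62.5-fold higher. CCL20, which attracts dendritic cells and lymphocytes, rose by 5.18 (SE 0.72, adjusted p = 0.0393), at least 30.3-fold. The neutrophil chemokine CXCL8 rose by 4.82 (SE 0.67, adjusted p = 0.0393), a 28.3-fold change. The transcription factors EGR1, ATF3, NR4A2 and NR4A1 rose by 4.17, 3.99, 3.17 and 2.84 (NR4A1 at least 5.99-fold) and the small GTPase RASD1 by 3.30. NFKBIZ, an atypical IkB protein, rose by 2.72, the matricellular genes CCN1 and CCN2 by 2.68 and 2.44, the MAPK phosphatase DUSP5 by 2.43, the phosphatase subunit PPP1R15A by 2.18 and the mRNA decay factor ZFP36 by 1.65. Of the 18, 3 were unnamed probes. The genes given here were higher than in control on both replicate numbers.

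Of the fixed lists, 12 of 27 passed at 1 h in A549 (13 with the replicate block), all 12 upward, and 6 of them kept the call with an estimated correlation. Among 26 measured immediate early transcription factors 6 rose, or 15 adjusted over the list alone (list adjusted p = 4.52e-42, and adjusted p = 0.018 with an estimated correlation). Among 25 NF-kB components and feedback regulators 1 rose, or 11 adjusted over the list alone (adjusted p = 4.31e-29, and adjusted p = 0.0178 with an estimated correlation). MAPK phosphatases and receptor tyrosine kinase feedback (1 of 20, list alone 6) had an adjusted p of 1.51e-18, and TGF-beta and YAP responsive genes (2 of 15, list alone 5) of 1.43e-10, each with adjusted p = 0.00694 under an estimated correlation. EGF receptor ligands (0 of 5, list alone 2, adjusted p = 8.94e-06) and aryl hydrocarbon receptor targets (0 of 8, list alone 1, adjusted p = 0.00155) also kept the call, at adjusted p = 0.0299 and 0.0496 with an estimated correlation. In the latter list CYP1A1 was not detected in A549 control (change 0.08). TIPARP, another member, passed with the block (1.16). Early response genes of mRNA decay and growth arrest (2 of 15, list alone 5, adjusted p = 4.12e-17) missed the threshold with an estimated correlation, at adjusted p = 0.0579. Chemokines (2 of 16, list alone 4) passed at adjusted p = 2.27e-07, but at adjusted p = 0.15 with an estimated correlation. So did adhesion molecules and inflammatory enzymes (0 of 17, list alone 1, adjusted p = 0.00379, then adjusted p = 0.15) and hypoxia and glycolysis genes (0 of 15, list alone 2, 0.00379, then adjusted p = 0.158). The call also ended for interleukins and other cytokines (0 of 22, list alone 0, 0.00427, then adjusted p = 0.377) and JAK-STAT feedback genes (0 of 14, list alone 0, 0.0106, then adjusted p = 0.299).

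With the replicate number as a block, 70 genes passed at 1 h in A549 (66 higher, 4 lower), among them the 18. The added genes include CXCL2 (3.91), CXCL1 (2.98), TNFAIP3 (2.80), PHLDA1 (1.97), HBEGF (1.83), IRF1 (1.82), PTGS2 (1.71), DUSP1 (1.68), IER3 (1.60), NFKBIA (1.59) and NFKBIE (1.55), with blocked adjusted p from 0.000465 to 0.0495, and downward AXIN2 (-1.46) and PKDCC (-0.92). IL6 was not detected in control and stood 4.39 above it on number 1 and 1.35 on number 2. It passed in neither model (adjusted p = 1 and 0.184). FOS (1.35), ICAM1 (0.10) and HMOX1 (-0.26) passed in neither. The count of 18 was 4 without either A549 control array and 3 and 4 without the A549 1 h arrays numbered 1 and 2. It was 10 and 9 without the A549 6 h arrays numbered 1 and 2, and 7 without either BEAS-2B 6 h array. FOSB and NR4A1 passed whichever single array was left out. CCL20 kept its call in 4 of these 12 fits, with a change of 4.27 to 6.06, and lost it without either A549 control, A549 1 h, BEAS-2B 1 h or BEAS-2B 6 h array. CXCL8 kept it in 6 (4.28 to 5.38), with losses without either A549 control, A549 1 h or BEAS-2B 6 h array. RASD1 kept it in 10, EGR1 and DUSP5 in 8, CCN2 in 7, PPP1R15A in 6, NFKBIZ and CCN1 in 4, NR4A2 in 3 and ATF3 and ZFP36 in 2. The count was 8 and 9 without all BEAS-2B arrays numbered 1 and 2, an alternative chosen after the data were seen.

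**Figure D1:**
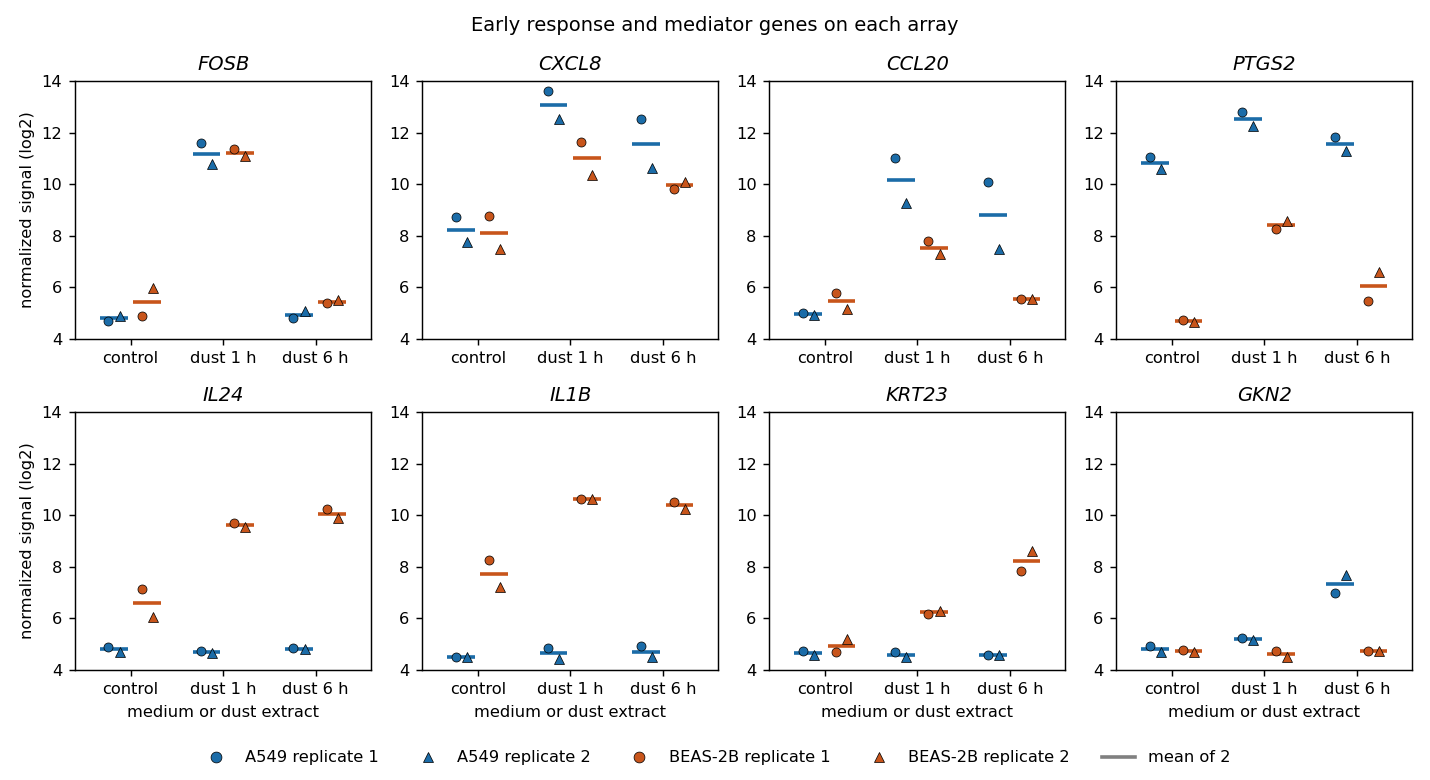
Normalized signal (log2) of 8 genes on each array, by condition (x axis), line (colour) and replicate number (symbol), with bars at the mean of 2 arrays. FOSB was near the detection limit in the control and 6 h groups of A549 and rose by 6.40 at 1 h, whereas IL24 and KRT23 rose in BEAS-2B at 6 h by 3.48 and 3.30 and GKN2 rose in A549 at 6 h by 2.50.

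In BEAS-2B, 25 features passed after 1 h of dust extract, 15 of them named, and all 25 were higher, among them FOSB, PTGS2, IL1A and IL1B. FOSB rose by 5.78 (SE 0.35, adjusted p = 0.000124). PTGS2, the inducible cyclooxygenase, rose by 3.73 (SE 0.36, adjusted p = 0.00244) from an undetected control level, at least 9.03-fold. The cytokine mRNAs IL24, IL1B, IL1A and LIF rose by 3.05 (SE 0.30, adjusted p = 0.0025), 2.90, 2.78 and 1.67. Feedback regulators of MAPK and EGF receptor signalling rose as well, with DUSP5 at 3.28 (SE 0.27, adjusted p = 0.00116), ERRFI1 at 2.62 and DUSP6 at 1.53. The pseudokinase TRIB1 rose by 2.88, CCN2 by 2.68, the epithelial transcription factor OVOL1 by 2.25 (at least 3.20-fold), ZFP36 by 1.72 and NR4A1 by 1.49 (at least 2.00-fold). The 10 unnamed probes include ILMN_2150856, which rose by 3.60.

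At 1 h in BEAS-2B 12 of 27 lists passed (13 with the block), all 12 upward, and 4 of them kept the call with an estimated correlation. Those 4 were immediate early transcription factors (2 of 26 rose, 16 adjusted over the list alone, adjusted p = 4.24e-32, and adjusted p = 0.0349 with an estimated correlation), MAPK phosphatases and receptor tyrosine kinase feedback (3 of 20, list alone 8, adjusted p = 2.36e-20, then adjusted p = 0.00808), TGF-beta and YAP responsive genes (1 of 15, list alone 7, 3.73e-09, then adjusted p = 0.00808) and adhesion molecules and inflammatory enzymes (1 of 17, list alone 6, 9.01e-09, then adjusted p = 0.0325). Interleukins and other cytokines (4 of 22, list alone 4, adjusted p = 6.46e-06) and NF-kB genes (0 of 25, list alone 2, adjusted p = 3.04e-06) both had adjusted p = 0.173 with an estimated correlation. Early response genes of mRNA decay and growth arrest (1 of 15, list alone 10, adjusted p = 5.81e-19) had adjusted p = 0.0637 with it. Chemokines (0 of 16, list alone 1, adjusted p = 0.000626) had adjusted p = 0.277 with it, EGF receptor ligands (0 of 5, list alone 1, 0.0151) adjusted p = 0.168 and hypoxia and glycolysis genes (0 of 15, list alone 0, 0.0218) adjusted p = 0.229. JAK-STAT feedback (0 of 14, list alone 4, adjusted p = 4.55e-05) and epithelial junction markers (0 of 17, list alone 1, adjusted p = 0.00747) both had adjusted p = 0.142 with it.

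With the block, 108 genes passed at 1 h in BEAS-2B (101 higher, 7 lower), including the 25. Added genes were HBEGF (2.88), CXCL8 (2.88), the prostaglandin receptor PTGER4 (2.85), ATF3 (2.81), FOS (2.12), tissue factor F3 (2.00), FOSL1 (1.93), PLAUR (1.93), ELF3 (1.86) and EGR1 (1.80), and downward FRAT2 (-1.14), ZSCAN2 (-1.12, with other probes of that gene at 0.03 and 0.23), INKA1 (-1.12) and RNF144B (-1.09). Their blocked adjusted p ran from 0.000481 to 0.0407. CCL20 (2.07), TNFAIP3 (2.20), IL6 (0.98), CXCL1 (0.71), HMOX1 (0.49), ICAM1 (0.17) and CYP1A1 (-0.15) passed in neither model. The count of 25 was 14 to 16 without any one of the 6 A549 arrays, 11 and 13 without the BEAS-2B 1 h arrays numbered 1 and 2 and 13 without BEAS-2B control replicate 2. FOSB, PTGS2, DUSP5, IL24, TRIB1 and OVOL1 passed in each case. Of the 12 fits that leave out an array, IL1B kept its call in 11 (not without BEAS-2B 1 h replicate 1), CCN2 in 9, LIF in 4, IL1A, ERRFI1 and ZFP36 in 2, and NR4A1 and DUSP6 in 0. Without all BEAS-2B arrays numbered 2 it was 5.

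At 1 h, 6 features passed upward in both lines (FOSB, DUSP5, CCN2, NR4A1, ZFP36 and the unnamed probe ILMN_2410145), against 0.0224 if the calls were independent (Fisher's exact test, two-sided, p = 3.6e-14). With the block 29 were shared of 66 and 101, against 0.332 (Fisher's exact test, p = 1.05e-50), including CXCL8, ATF3, EGR1, HBEGF, PTGS2 and TRIB1. The calls of both lines came from 1 fit with a variance per gene shared by the lines, and genes vary together. The calls are thus not independent, and both p-values can be too small. With each line fitted alone 9 features passed in A549 and 1 in BEAS-2B, and 1 was shared. The overlap of 6 was 1 without either A549 control array or A549 1 h replicate 1, 2 without BEAS-2B control replicate 2, and 3 without A549 1 h replicate 2, BEAS-2B 1 h replicate 1 or either BEAS-2B 6 h array. Across all genes, which are not independent replicates, the 1 h changes of the lines had a Pearson correlation of 0.28 and a rank correlation of 0.14. For the 6 h changes these were 0.13 and 0.11.

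**Figure D2:**
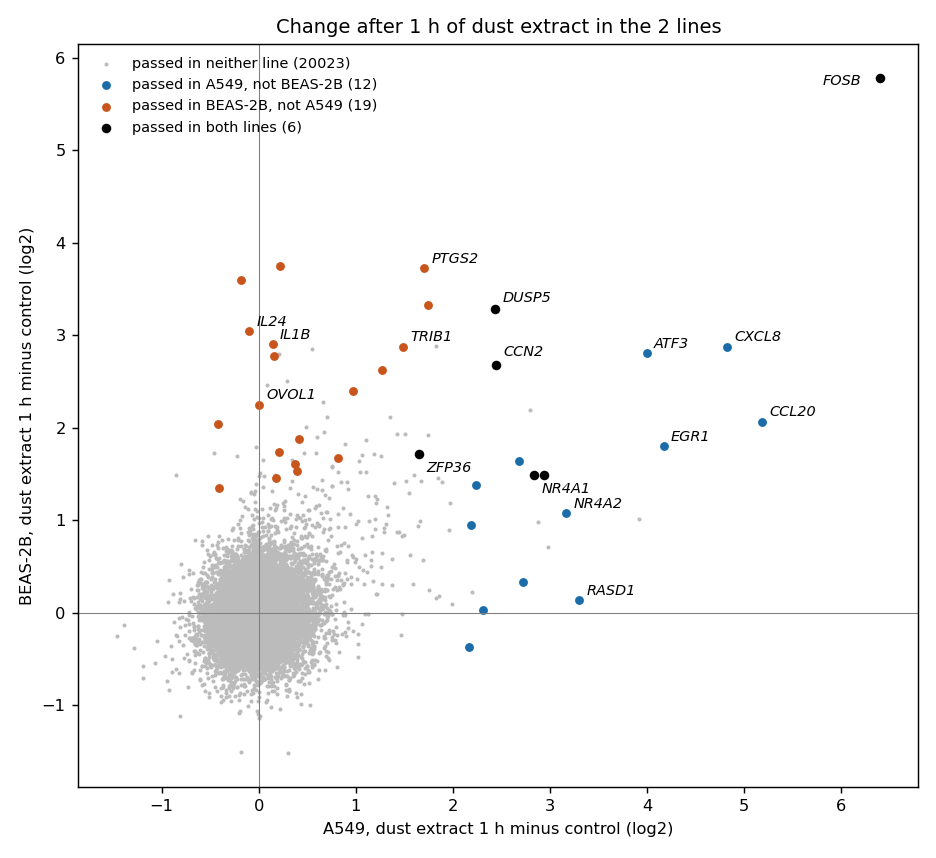
Change after 1 h of dust extract against control (log2) in A549 (x axis) and BEAS-2B (y axis), 1 point per gene or unnamed probe, coloured by the line in which it passed. FOSB lies at 6.40 and 5.78, CCL20 and CXCL8 lie further right (5.18 and 4.82 in A549) than up (2.07 and 2.88 in BEAS-2B), and IL24 lies near 0 in A549 (-0.10) and at 3.05 in BEAS-2B.

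After 6 h in A549, 1 gene passed, GKN2, a secreted gastrokine, with a rise of 2.50 (SE 0.24, adjusted p = 0.0108) that is at least 4.31-fold. With quantile normalization without background correction 1 feature passed, and it was not GKN2. At an unadjusted p under 0.05 there were 755 features. With the block 56 genes passed (48 higher, 8 lower). They include CCL20 at 3.83 (at least 11.9-fold, blocked adjusted p = 0.0118), the TNF family cytokine LTB at 3.63 (at least 7.10-fold, another probe at 1.01), CXCL8 at 3.34, the lectin-like receptor OLR1 at 2.80 (at least 4.59-fold), IL32 at 2.48, CXCL5 at 2.38, CCL2 and CXCL2 at 2.02 each, mitochondrial superoxide dismutase SOD2 at 1.94, NFKB2 at 1.77 and RELB at 1.64. Lower with the block were the bile acid conjugating enzyme BAAT (-2.01), NCALD (-1.46), TFCP2L1 (-1.22, at least 1.67-fold lower), WIPF1 (-1.13, at least 2.06-fold lower) and BCO1 (-1.04). CXCL1 (2.14), IL6 (1.44), TNFAIP3 (1.01), PTGS2 (0.72), ATF3 (0.24), FOS (0.12), EGR1 (-0.16), HMOX1 (-0.96), ICAM1 (0.21) and CYP1A1 (0.05) passed in neither model. Without either A549 control array the single call was lost. Without A549 6 h replicate 2 there were 3 calls, and 2 without BEAS-2B 1 h replicate 2. Without all BEAS-2B arrays of either number 0 passed.

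Of the lists, 6 passed at 6 h in A549 (9 with the block), all 6 upward, and 0 kept the call with an estimated correlation. NF-kB genes (0 of 25 rose, 6 adjusted over the list alone, adjusted p = 4.25e-10) and adhesion molecules and inflammatory enzymes (0 of 17, list alone 1, adjusted p = 0.000697) had adjusted p = 0.141 with an estimated correlation. Chemokines (0 of 16, list alone 3, adjusted p = 2.25e-06) had adjusted p = 0.249 with it. MAPK phosphatases (0 of 20, list alone 1, adjusted p = 3.58e-05), EGF receptor ligands (0 of 5, list alone 2, adjusted p = 0.000274) and TGF-beta and YAP responsive genes (0 of 15, list alone 3, adjusted p = 0.00322) all had adjusted p = 0.123 with it.

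After 6 h in BEAS-2B, 13 features passed (12 higher, 1 lower), 10 of them named, with the cytokine genes IL24 and IL1B and the keratin gene KRT23 among the higher. IL24 rose by 3.48 (SE 0.30, adjusted p = 0.00165), an 11.2-fold change, and IL1B by 2.67. The epithelial keratin KRT23 rose by 3.30 (SE 0.27, adjusted p = 0.00133) from an undetected control level, at least 7.94-fold. MALL, a membrane raft protein, rose by 3.44 (SE 0.36, adjusted p = 0.00548), the metalloprotease ADAM8 by 2.41, SPOCD1 by 2.37, the transcription factor CREB5 by 1.93 (another probe at 0.44), C1orf74 by 1.78 and PALM2 by 1.48. KANK4 fell by 2.30 (SE 0.34, adjusted p = 0.0481). The panel genes CXCL8 (1.84), PTGS2 (1.34), TNFAIP3 (0.84), EGR1 (0.69), ICAM1 (0.50), CXCL1 (0.46), HMOX1 (0.34), FOS (0.29), IL6 (0.22), CCL20 (0.08), ATF3 (-0.58) and CYP1A1 (-1.44) did not pass with or without the block.

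With the block 114 genes passed at 6 h in BEAS-2B (89 higher, 25 lower), including the 13. Added genes include the activin antagonist FST (2.62), the crosslinking enzyme TGM2 (2.51), GLIPR1 (2.44), the secretory granule protein SCG5 (2.37), FOXA2 (1.51) and S100A2 (1.47). Downward were the transcription factors OVOL2 (-2.39) and LMO1 (-1.45, at least 1.77-fold lower), TNNI2 (-1.81), TRIM6 (-1.74), MMP28 (-1.53, another probe at -0.03), the growth factor receptor FGFR3 (-1.44) and WNT10A (-1.32), with blocked adjusted p from 0.000797 to 0.031. Upward calls were made for 2 lists (5 lists passed with the block), MAPK phosphatases and receptor tyrosine kinase feedback (0 of 20, list alone 2) and adhesion molecules and inflammatory enzymes (0 of 17, list alone 0), both at adjusted p = 6.32e-05 and at adjusted p = 0.191 with an estimated correlation. The interferon-stimulated genes, whose level differed between the BEAS-2B arrays numbered 1 and 2 in every condition, had a median change of -0.94 on number 1 and -0.14 on number 2 (adjusted p = 0.243, with the block adjusted p = 2.6e-08, and with block and estimated correlation adjusted p = 0.491). The count of 13 was 8 without A549 control or 6 h replicate 1 and 6 and 7 without A549 control and 6 h replicate 2. It was 5 and 6 without the BEAS-2B 6 h arrays numbered 1 and 2 and 4 without BEAS-2B control replicate 2 or without all BEAS-2B arrays numbered 2. IL24 and KRT23 passed whichever single array was left out. Of these 12 fits MALL kept its call in 11 (not without BEAS-2B control replicate 2), C1orf74 in 9, IL1B in 8, ADAM8 in 3, PALM2 and KANK4 in 2, and SPOCD1 and CREB5 in 1.

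**Figure D3:**
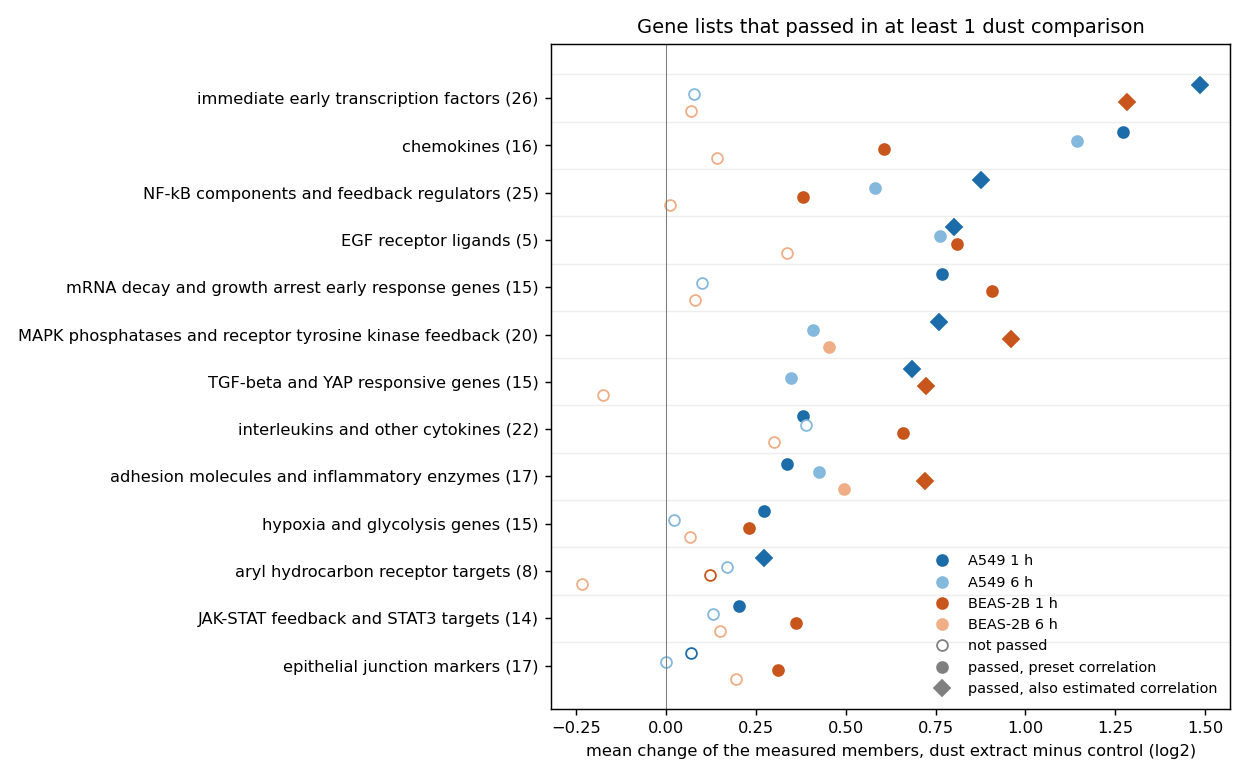
Mean change of the measured members (log2, dust extract minus control) of each list that passed in at least 1 of 4 dust comparisons, with the number of measured members in parentheses. Filled symbols passed with the preset correlation, and diamonds also passed with an estimated one, as immediate early transcription factors did at 1 h in A549 (adjusted p = 0.018) and in BEAS-2B (adjusted p = 0.0349).

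The arrays at 6 h were compared directly with those at 1 h to ask which changes faded or grew with time. In both lines FOSB fell back. In A549 7 features passed (1 higher, 6 lower): FOSB fell by 6.25 (SE 0.35, adjusted p = 5.56e-05, at least 60.9-fold lower), EGR1 by 4.33, CCN2 by 2.36, NR4A1 by 2.30 and ETS2 by 1.5, while GKN2 rose by 2.15. With the block 47 passed (14 higher, 33 lower), with LTB (2.71), IL32 (1.72), SOD2 (1.47) and CXCL5 (1.31) upward and ATF3 (-3.76), JUN (-2.67), NR4A2 (-2.64), PRDM1 (-2.53), CCN1 (-2.42) and CXCL2 (-1.89) downward. The changes of CXCL8 (-1.48), CCL20 (-1.35), IL6 (-1.43), TNFAIP3 (-1.79), FOS (-1.23), CXCL1 (-0.84), PTGS2 (-0.99), HMOX1 (-0.70), ICAM1 (0.11) and CYP1A1 (-0.03) passed in neither. The count of 7 was 4 without either A549 control array, 2 without A549 1 h replicate 1 and 3 without either A549 6 h array, and FOSB passed whichever was left out. Of the 12 fits NR4A1 kept its call in 10, GKN2 in 9, EGR1 and ETS2 in 6 and CCN2 in 1.

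In BEAS-2B 12 features passed between 1 h and 6 h (2 higher, 10 lower). FOSB fell by 5.78 (SE 0.35, adjusted p = 0.000124), CCN2 by 3.18, OVOL1 by 2.23 (at least 3.17-fold lower), DUSP5 by 2.21, the enamel-associated gene TUFT1 by 1.79 and TENT5B by 1.42. KRT23 rose by 2.00 and FRAT2 by 1.34. With the block 135 passed (55 higher, 80 lower). Upward were SCG5 (2.42), MALL (2.16), TGM2 (2.05) and FOXA2 (1.12). Downward were ATF3 (-3.39), PTGER4 (-2.97), PTGS2 (-2.39), NCOA7 (-2.26), KLF10 (-1.90), FOS (-1.83), FOXA1 (-1.77), ELF3 (-1.71), DUSP1 (-1.59) and EGR1 (-1.11). CXCL8 (-1.04), CCL20 (-1.99), IL6 (-0.76), TNFAIP3 (-1.35), CXCL1 (-0.25), HMOX1 (-0.15), ICAM1 (0.32) and CYP1A1 (-1.29) passed in neither. The count of 12 was 5 to 7 without 6 of the arrays (A549 control, 1 h and 6 h of both numbers) or a BEAS-2B 1 h array, 1 and 2 without the BEAS-2B 6 h arrays numbered 1 and 2, and 19 without either BEAS-2B control array, and FOSB passed in each case. Of the 12 fits OVOL1 kept its call in 11, CCN2 in 9, DUSP5 in 7, TENT5B in 3, KRT23 and TUFT1 in 2 and FRAT2 in 0. It was 1 and 5 without all BEAS-2B arrays numbered 1 and 2.

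For lists between 1 h and 6 h, 6 passed in each line (8 in A549 and 11 in BEAS-2B with the block). In A549 they were immediate early transcription factors (3 of 26 fell, 14 adjusted over the list alone, adjusted p = 8.85e-30, and adjusted p = 0.166 with an estimated correlation) and NF-kB genes (0 of 25, list alone 4, downward at 0.00113, then adjusted p = 0.461). The 3 other downward lists were mRNA decay (0 of 15, list alone 4, 6.26e-11), MAPK phosphatases (0 of 20, list alone 0, 0.000171) and TGF-beta and YAP responsive genes (1 of 15, list alone 4 lower and 1 higher, 0.0421), each at adjusted p = 0.240 with an estimated correlation. For the last of these the median was 0.01 while the mean was -0.34 and the test was downward. Metallothioneins were tested upward in A549 (0 of 7, list alone 1, adjusted p = 0.0421, and adjusted p = 0.419 with an estimated correlation). In BEAS-2B the downward list of TGF-beta and YAP responsive genes (1 of 15, list alone 6, adjusted p = 7.61e-11) kept its call with an estimated correlation (adjusted p = 0.0096). Immediate early transcription factors (1 of 26, list alone 12, adjusted p = 1.45e-22) and MAPK phosphatases (1 of 20, list alone 5, adjusted p = 2.31e-06) had adjusted p = 0.104 with it, mRNA decay (0 of 15, list alone 8, 6.98e-15) adjusted p = 0.131, NF-kB genes (0 of 25, list alone 1, 8.53e-05) adjusted p = 0.434 and chemokines (0 of 16, list alone 0, 0.0477) adjusted p = 0.604. The chemokine call turned direction without BEAS-2B 1 h replicate 1 (adjusted p = 0.788). The list median went from 6.57 to 5.56 on number 1 and from 5.58 to 5.47 on number 2.

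The test of the difference between lines asked which changes were not alike in A549 and BEAS-2B. At 6 h KRT23 and the unnamed probe ILMN_2150856 passed, with changes larger in BEAS-2B by 3.40 (SE 0.38) and 3.99 (SE 0.45), both at adjusted p = 0.0299. For KRT23 the difference was 3.33 on number 1 and 3.47 on number 2, and the call was kept in 2 of the 12 fits that leave out an array (without BEAS-2B control replicate 2 or BEAS-2B 6 h replicate 1). The values of KRT23 by number rest on arrays that are not paired between lines. ILMN_2150856 was named after its values were seen. IL24 (3.46, adjusted p = 0.0507) and GKN2 (-2.48, adjusted p = 0.0792) missed the threshold without the block and passed with it (adjusted p = 0.0081 and 0.0327). With the block 21 passed at 6 h. The difference (BEAS-2B minus A549) was positive for 10, such as SCG5 (2.51), ADAM8 (2.49), IL1B (2.46), FOXA2 (1.83) and BAAT (2.07), which with the block fell by 2.01 in A549. It was negative for 11, such as LTB (-3.69), IL32 (-2.46), CXCL5 (-2.38), VSIR (-2.25), MMP28 (-2.09, another probe at -0.06), TNNI2 (-2.02) and TMEM158 (-1.84). At 1 h limma called 0 genes (497 at an unadjusted p under 0.05), and 8 with the block (6 and 2), among them IL24 (3.15), IL1B (2.76) and OVOL1 (2.24), larger in BEAS-2B, and RASD1 (-3.16) and EGR1 (-2.37), larger in A549. For CCL20 the difference was -3.12 at 1 h and -3.75 at 6 h, for CXCL8 -1.95 and -1.5, for PTGS2 2.02 and 0.62, for IL6 -1.89 and -1.22 and for CXCL1 -2.27 and -1.68, and none of these 5 passed in either model. Untreated BEAS-2B already held LTB, IL32, EGR1 and IL1B at higher levels than A549, and CXCL5 and PTGS2 at lower ones. These differences in change therefore do not show which line reached the higher level. The part played by the starting level was not tested.

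In the difference between lines 2 lists passed at 1 h and 3 at 6 h (4 each time with the block). The difference in NF-kB genes was downward, that is below 0 for BEAS-2B minus A549, at 1 h (adjusted p = 7.86e-06, median -0.42) and at 6 h (adjusted p = 1.27e-05, median -0.40), with 0 of 25 members passing and 2 adjusted over the list alone each time. At 1 h the list passed upward in both lines (medians 0.72 in A549 and 0.32 in BEAS-2B), and at 6 h in A549 (0.38) but not in BEAS-2B (0.01, adjusted p = 0.966). With an estimated correlation these were adjusted p = 0.780 and adjusted p = 0.826. Adhesion molecules and inflammatory enzymes differed upward at 1 h (0 of 17, list alone 1, adjusted p = 0.00355, and adjusted p = 0.780 with an estimated correlation). At 6 h chemokines (0 of 16, list alone 2, adjusted p = 0.00635) and TGF-beta and YAP responsive genes (0 of 15, list alone 1, adjusted p = 0.00108) differed downward, at adjusted p = 0.888 and adjusted p = 0.158 with an estimated correlation. The 6 h count of 2 was 0 without any one of 9 arrays, the exceptions being both BEAS-2B control arrays and BEAS-2B 6 h replicate 1, and 6 and 0 without all BEAS-2B arrays numbered 1 and 2. The 1 h count of 0 was 5 without BEAS-2B control replicate 1 and 4 without all BEAS-2B arrays numbered 1.

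Untreated, the lines differed in 4481 features (2169 higher and 2312 lower in BEAS-2B). Among the largest falls in BEAS-2B were the aldo-keto reductase AKR1B10 at -9.66 (SE 0.18, adjusted p = 2.99e-10, at least 554-fold lower), the aldehyde dehydrogenase ALDH1A1 at -9.49, AKR1C2 at -9.47 (at least 668-fold lower), the selenoenzyme GPX2 at -8.53 (at least 307-fold lower), AKR1C4 at -8.46, CA12 at -8.05 and AKR1B15 and GCNT3 at -7.73 each (at least 136-fold and 117-fold lower). The probes of AKR1C4 and AKR1B15 may also bind transcripts of the related AKR1C2 and AKR1B10, which was not tested. ALDH3A1 (-7.26) was lower too. The NRF2 target list, which shares AKR1B10 with the alveolar and secretory list, was lower (15 of 16 members, list alone 16, adjusted p = 2.75e-16, and adjusted p = 0.0243 with an estimated correlation), with HMOX1 at -3.35, NQO1 at -1.97 and SLC7A11 at -3.64 (at least 7.09-fold lower). Alveolar and secretory markers were lower (8 of 12, 1 higher, list alone 8 and 1, adjusted p = 5.63e-06, and adjusted p = 0.184 with an estimated correlation), among them AGR2 (-5.24) and CEACAM6 (-6.03, at least 41.2-fold lower). CEACAM6 lost its call without A549 control replicate 1 (-7.93 to -4.10 over the fits that leave out an array), and AGR2 without that array or BEAS-2B control replicate 1 (-6.35 to -4.13). PTGS2 (-6.14, at least 48.0-fold) and CXCL5 (-5.09, at least 25.5-fold) were lower in BEAS-2B.

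Higher in untreated BEAS-2B were LTB by 7.50 (SE 0.60, adjusted p = 1.06e-05, at least 104-fold), MT1E by 7.02 (another probe at 1.08), HLA-B by 6.77 (at least 80.4-fold), COL8A1 by 6.26 (at least 44.0-fold), IL32 by 4.83, EGR1 by 3.93, IL6 by 3.85 (at least 10.2-fold), IL1B by 3.22 (at least 5.66-fold), TNFAIP3 by 2.42, ATF3 by 2.31 and ICAM1 by 1.07 (at least 1.57-fold). IL6 (2.95 to 4.75), TNFAIP3 (1.64 to 3.21), ATF3 (1.27 to 3.34) and ICAM1 (0.86 to 1.28) each lost their call without either A549 control array or BEAS-2B control replicate 1. Over the fits that leave out an array HLA-B ran from 5.69 to 7.85 and COL8A1 from 5.48 to 7.05. CXCL8 (-0.12), CCL20 (0.51), CXCL1 (-0.39), FOS (-0.52) and CYP1A1 (1.56) did not pass. Metallothioneins (6 of 7 higher, list alone 6, adjusted p = 1.35e-07) and airway basal and keratin markers (7 of 10, list alone 8, adjusted p = 4.34e-07), such as CDH3 (5.02, at least 19.6-fold), S100A2 (4.95, at least 23.2-fold) and KRT5 (3.13, at least 5.14-fold), kept their calls with an estimated correlation (adjusted p = 0.0356 and 0.0243). NF-kB genes (12 of 25 higher, 1 lower, list alone 12 and 1, adjusted p = 0.00406, and adjusted p = 0.515 with an estimated correlation) and cell cycle genes (9 of 27 higher, 1 lower, list alone 10 and 2, adjusted p = 0.00139, and adjusted p = 0.554 with an estimated correlation) were higher. Interferon-stimulated genes were higher as well (11 of 32, list alone 14, adjusted p = 1.19e-07, and adjusted p = 0.554 with an estimated correlation), with IFITM1 at 7.30, MX1 at 7.10, IFITM3 at 6.78 and ISG15 at 6.59. MX1 (5.03 to 9.19) lost its call without either A549 control array or BEAS-2B control replicate 1, and ISG15 (4.55 to 8.65) without A549 control replicate 1 or BEAS-2B control replicate 1. The median difference of the interferon-stimulated list was 6.00 on number 1 and 1.81 on number 2, although the numbers are not paired between lines. Without A549 control replicate 1 or 2 the count of 4481 was 2730 and 2819, and without BEAS-2B control replicate 1 it was 2917.

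**Figure D4:**
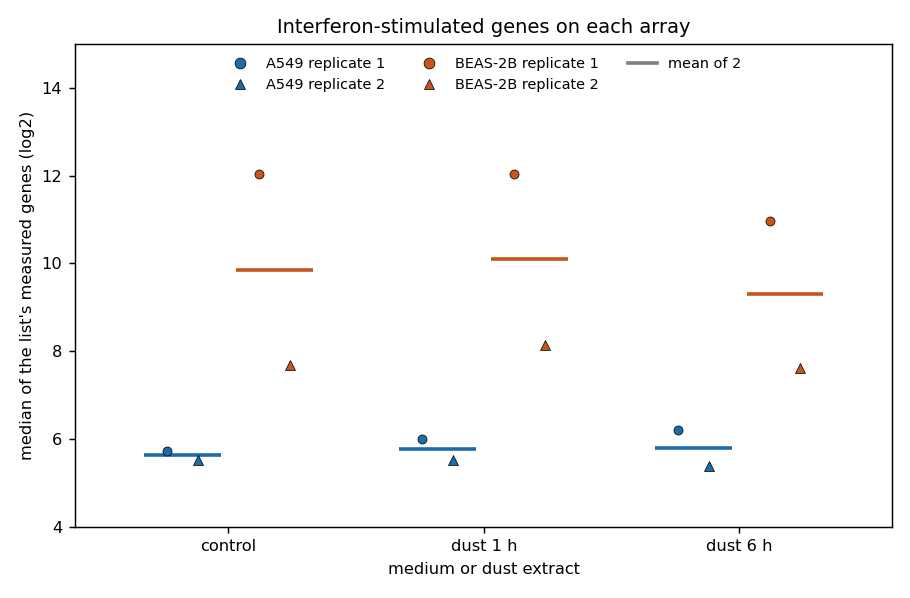
Median normalized signal (log2) of the 32 measured interferon-stimulated genes on each array, by condition (x axis), line (colour) and replicate number (symbol), with bars at the mean of 2 arrays. BEAS-2B arrays numbered 1 lie between 10.98 and 12.05, those numbered 2 between 7.61 and 8.14, and A549 arrays between 5.39 and 6.22.

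In none of the 9 comparisons did 8 of the lists pass without the block and with the preset correlation. Their lowest adjusted p was 0.0534 for mesenchymal markers and 0.0717 for cytosolic heat shock proteins (both between untreated lines), 0.0851 for cholesterol synthesis (BEAS-2B between 1 h and 6 h) and 0.0877 for antimicrobial, acute phase and mucin genes (A549 at 6 h). It was 0.152 for the unfolded protein and integrated stress response (A549 at 6 h), 0.231 for pattern recognition and protease receptors (BEAS-2B at 1 h), 0.265 for ribosomal proteins (A549 at 6 h) and 0.719 for blood leukocyte and macrophage markers (A549 at 1 h).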

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

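In this part, the test of members that vary together was chosen after the result was seen. Of 20060 features, 2 had changes at 6 h that differed between A549 and BEAS-2B in a test of the difference, KRT23 by 3.40 and the unnamed probe ILMN_2150856 by 3.99. The same test, on lists, called adhesion molecules and inflammatory enzymes at 1 h (median difference 0.14) and chemokines and TGF-beta and YAP responsive genes at 6 h (both with a median difference of -0.57). With an estimated correlation none of these 3 list calls was kept (adjusted p = 0.780, 0.888 and 0.158). It also called NF-kB components and feedback regulators at 1 h (-0.42) and at 6 h (-0.40), again not kept with an estimated correlation (adjusted p = 0.780 and 0.826).

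The median change of NF-kB genes at 1 h was 1.07 on number 1 and 0.47 on number 2 in A549, and 0.33 and 0.29 in BEAS-2B. The median level of the list went from 6.58 to 7.78 and from 6.68 to 7.31 in A549, and from 7.98 to 8.58 and from 7.45 to 8.14 in BEAS-2B. By that measure the rise on A549 number 1 was above both BEAS-2B rises, and that on A549 number 2 lay between them. The numbers are not paired between lines. Saturation of the signal is argued against, since 0% of the 25 members were among the brightest 1% of genes in BEAS-2B at 1 h. The normalization is argued against as the cause, since the highest adjusted p over 3 other sources or normalizations was 0.000163. Of these only median centring (adjusted p = 1.71e-07) departs from quantile normalization, so the alternatives were not 3 separate tests. Members that vary together between replicates may account for the call, because with a correlation estimated from the residuals the adjusted p was 0.780. A difference between the lines themselves stays open, as untested beyond this interaction.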

How the results depend on the processing

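The alternatives that leave out all BEAS-2B arrays of a replicate number were chosen after seeing the data. None of the 153 calls of named genes reversed under any alternative in which it was tested, single arrays left out included. With the block, the intensity trend, array weights or each line alone the estimated changes stay the same, so no reversal was possible there. The 153 were picked by the naming rule, and 53 of them belong to the dust and time comparisons within a line. Nearly all others compare the untreated lines. Of the 153, 133 were kept with quantile normalization without background correction, 134 with median centring, 136 with the series matrix values, 116 with no filter on dim probes, 144 with a stricter filter and 141 with array weights. With each line fitted alone 14 of 53 were kept, and with the replicate block all 153. Of 56 list calls, 14 were kept with an estimated correlation. Fry, which tests a list against no change rather than against other genes, called 19 of them. Over the 4 dust comparisons the lists passing were 10 with an estimated correlation and 10 with fry, against 32.

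In this paragraph and the next, counts that moved less in proportion are left out, and a similar count can hold other genes. At 1 h, for example, quantile normalization without background correction gave 36 genes in BEAS-2B against 25, with 24 shared. In A549 it gave 16 against 18, with 12 shared. Between 1 h and 6 h in BEAS-2B it gave 21 genes. Median centring gave 16 in BEAS-2B at 1 h, 11 in A549 and 4 in BEAS-2B between 1 h and 6 h, 3 and 4 that differed between lines at 1 h and 6 h, and an overlap of 3. It also lowered the share of higher genes between untreated lines to 36.1% from 48.4%. The series matrix values gave 3 in A549 at 6 h, 20 in BEAS-2B between 1 h and 6 h and 2 that differed between lines at 1 h. With no filter on dim probes there were 5 in A549 at 1 h, 7 in BEAS-2B at 6 h, 0 that differed between lines at 6 h and an overlap of 3, and with a stricter filter 9 in A549 at 1 h. Array weights gave 2 in A549 at 6 h, 16 in BEAS-2B at 1 h and 14 in A549 between 1 h and 6 h. For these settings the cause was not tested. A threshold of 0.01 left an overlap of 2, by its construction.

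With each line fitted alone there were 9 and 0 genes in A549 at 1 h and 6 h, and 1 and 0 in BEAS-2B. There were 2 in BEAS-2B between the times and an overlap of 1. These fits have fewer residual degrees of freedom, and each line has its own variance. The standard deviation of the difference between replicates was 0.510 to 0.568 in the BEAS-2B groups and 0.405 to 0.431 in A549. The model of all arrays shares 1 variance per gene, so its BEAS-2B p-values do not measure the spread of BEAS-2B alone. With the replicate block, which removes what the arrays of a number share within a line, the counts were 70 and 56 in A549 at 1 h and 6 h, 108 and 114 in BEAS-2B, 47 and 135 between the times, 8 and 21 for the difference between lines at 1 h and 6 h, and an overlap of 29. Without the BEAS-2B arrays numbered 1 there were 8 and 0 in A549 at 1 h and 6 h, 1 in BEAS-2B between the times, 4 and 6 for the difference between lines and an overlap of 3. Without those numbered 2 there were 9 and 0 in A549, 5 and 4 in BEAS-2B at 1 h and 6 h, 5 between the times, 0 for the difference at 6 h and an overlap of 1.

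Leaving out each array in turn, which leaves fewer residual degrees of freedom and 1 group with a lone array that is assumed to vary like the other groups, gave 3 to 16 genes in A549 at 1 h, 0 to 3 at 6 h and 2 to 9 between them. In BEAS-2B it gave 11 to 36, 4 to 14 and 1 to 19. The difference between lines ranged from 0 to 5 at 1 h and 0 to 3 at 6 h, the untreated lines from 2730 to 4585, the lists passing from 29 to 47 and the overlap from 1 to 5. The interferon-stimulated genes had adjusted p from 2.45e-13 to 0.264 in BEAS-2B at 6 h, from 3.03e-11 to 0.643 for the difference between lines at 6 h and from 2.11e-12 to 0.222 in BEAS-2B between 1 h and 6 h. Chemokines had adjusted p from 3.00e-05 to 0.788 in BEAS-2B between 1 h and 6 h. Direction reversed for the interferon list without BEAS-2B control replicate 1 at 6 h (adjusted p = 4.94e-05) and in the difference at 6 h (adjusted p = 0.0281), and without BEAS-2B 1 h replicate 1 between 1 h and 6 h (adjusted p = 0.00181). In each case the lone array left is numbered 2, where this list is low. Chemokines reversed too, without passing, when BEAS-2B 1 h replicate 1 was left out. The lone 1 h array is then also numbered 2, where the median of this list was 5.58, against 6.57 on number 1. Whether that gap accounts for the reversal was not tested. Of 47320 probes 24467 passed the detection filter, so changes of the dimmer probes were tested only in the setting with no filter.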

Other observations

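The replicate numbers set apart a group of genes in BEAS-2B, which was looked for after the values were seen, and the tests of leukocyte RNA and of A549 RNA were chosen after the result was seen. In each of 3 conditions 52 features were at least 4-fold higher on number 1 and 13 on number 2, against 17 and 3 in A549. Of the 52, 24 are on the interferon list, with OAS2 at a mean difference of 6.64, IFI27 at 6.59 and IFI44L at 6.23. Others outside the list are the transporter SLC15A3 (5.01), CEACAM1 (4.48), the antiviral TRIM22 (4.35), the chemokines CCL5 (4.26) and CXCL10 (3.63) and the protease MMP9 (3.37). Higher on number 2 were the calgranulin S100A9 (-3.40), ACO1 (-2.68), the lipogenic regulator MLXIPL (-2.67), CCL2 (-2.49), AGR2 (-2.44) and ALDH3A1 (-2.40). IFNB1, the type I interferon gene, was at 6.27, 8.01 and 4.90 in control, 1 h and 6 h on number 1, and at 4.50, 4.51 and 4.49 on number 2. The 6 h value on number 1 and all values on number 2 lay below the dimmest detected probe of their arrays (5.22 to 5.28). IFNB1 was thus not detected there.

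Interferon-stimulated genes stood high on the BEAS-2B arrays numbered 1, the control included, although the labels name no treatment that separates the numbers. Chip position does separate them (G to I for number 1, J to L for number 2), and its part was not tested. In BEAS-2B control the list's members lay a median of 3.65 higher on number 1 than on number 2. The highest of the random lists matched on level had 0.28, so genes of the same level did not share the gap. Quantile normalization had already removed effects of brightness or scan that are shared by a level, so this comparison was no separate test of them. RNA of blood leukocytes or macrophages is argued against, since the 8 measured genes of that list differed by a median of -0.0651 and were at most 0.77 higher. HBB among them is a red blood cell gene. ITGAM, CSF1R, FCGR3A and MS4A1 lay below the dimmest detected probe of the control array numbered 1 (5.27). LYZ stayed at 6.51 and CD14 differed by -1.52, while MX1 and ISG15 were at 14.5 and 14.4. RNA of A549 cells could not raise these genes, as A549 control held the list -6.40 below BEAS-2B control number 1. A state of the cells of that number may therefore differ, a hypothesis found and examined on the same arrays, and no biological explanation was tested because the labels do not say what the numbers mark.

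On the BEAS-2B arrays numbered 1 the interferon-stimulated genes were lower at 6 h than in control, by a median of -0.94, with 32 of 32 members lower, against 20 of 32 on number 2. The normalization is argued against, since the medians under 3 other sources or normalizations ran from -0.94 to -0.91. Of these only median centring departs from quantile normalization, so they were not 3 separate tests. The lowest of the random lists matched on level had a median of -0.27, so genes of the same level did not share the fall. Quantile normalization had already removed a loss common to bright probes, so this comparison was no separate test of such a loss. A decline that follows the high starting level on that number may be a candidate explanation, and whether dust extract or time in culture goes with it was not tested, because the labels give no time point for the control arrays.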
